A study of Mus musculus with 6 samples.

How the data were processed

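RNA sequencing was done on nucleus accumbens tissue of C57BL/6 mice after 7 daily injections of cocaine or saline, in 3 libraries per group. Per the submitters' processing notes the tools were TopHat2 2.0.6 and Cufflinks 2.0.2 and the genome build was NCBIM37. Their settings, the gene annotation, the read length and the strand setting are not given in the sources used here. RNA was isolated and libraries were prepared with commercial kits, per the labels' protocols. The treatment text of the saline libraries repeats the cocaine protocol, and their treatment label, which says saline, was used for the grouping.

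A single table for the whole series was analysed. Per the file headers its first sample is saline and its second cocaine, and its layout is that of a Cuffdiff gene table. The group values were treated as FPKM made by the authors, since that is what such a table holds; the unit is not written in the file. Each is a group value over the libraries, made by the authors and deposited with no value per library. The log2 fold change, cocaine over saline, was deposited by the authors, and values recomputed from the group values lay within 3.81e-05 of it, records marked as failed left out. The p-value and q-value of each record come from the authors' own test and were copied as deposited. The file labels every record as protein-coding. FPKM divides fragments by transcript length and by the library total, so a rise in a few abundant transcripts lowers the values of the others. The 2 highest records held 19.0% of summed FPKM in the saline group and 19.4% in the cocaine group. The read depth per library is unknown, so no counting interval and no detection floor was computed.

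Records marked as tested were used, 14959 of 21540, and a gene was called at the deposited q < 0.05. The table holds 21203 symbols and 21290 gene identifiers, and 185 symbols have more than 1 record, none of them called. For gene lists the record with the highest mean FPKM was used per symbol, and members of at least 1 FPKM in the higher group entered, 12825 genes in all. The design named a test per library on a log scale as an option in case the table held such values, and it was not run. Named genes followed a rule written before the data were examined: the 10 largest rises and the 10 largest falls past the threshold among genes of at least 1 FPKM with a proper name, up to 4 called members of each fixed list with the smallest q, and always Tet1, Tet2, Tet3, Fos, Fosb, Arc, Egr1, Bdnf, Drd1a, Drd2 and Ttr. A few other genes are named as list members, chosen after their values were seen.

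The 28 gene lists were also written before the data were examined. They cover immediate-early and delayed activity genes, markers of the neurons, glia, vessels, blood and choroid plexus that the tissue could hold, cytosine modification, chromatin, dopamine, glutamate, GABA and neuropeptide genes, glucocorticoid and clock genes, chaperones, spine regulators, ribosomal proteins and respiratory chain genes. Some genes stand in several lists, such as Per1 in 3. For each list of at least 5 members the median log2 fold change was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins. This is a permutation of gene labels, not of libraries, and its two-sided p, called a gene-permutation p, was adjusted by Benjamini-Hochberg over the 28 lists, and 0.0002 is the smallest p these lists can give. This describes these libraries, since genes are not replicates. Calls were compared with the other tested genes of at least 1 FPKM by a two-sided Fisher's exact test, adjusted over the 28 lists, and the deposited p-values were also adjusted over each list alone. As an alternative, limma's cameraPR (limma 3.58.1, R 4.3.3) was run with preset correlations of 0.01 and 0.05. The table has no test statistic column, so a signed normal score from the deposited p-value was used, with a p listed as 0 set to the smallest p above 0. A correlation between genes could not be estimated without values per library, so no call with an estimated correlation can be given.

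GC content and length came from the longest transcript of each gene in GENCODE mouse release 21, matched by Ensembl identifier. That annotation belongs to a later build than the authors', so no coordinates are printed. GC content and length were found for 12566 genes, 98.0% of those of at least 1 FPKM. The trend was removed by subtracting the median log2 fold change of each of 10 GC by 10 length cells, and lists were then compared with random lists matched in 5 GC, 3 length and 5 FPKM strata. These corrections were added after seeing the data. So were lists of 4 kinds of genes (neuroblast markers, voltage-gated channels, tubulins and actins, and a second set of choroid plexus markers) and a subset of 5 immediate-early genes mostly expressed in neurons. The called genes that prompted the neuroblast, channel and tubulin lists were left out of them.

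Other alternatives, all written before the data were examined, were q thresholds of 0.01 and 0.10, a recomputed Benjamini-Hochberg adjustment, minimum FPKM values, fold minimums of 0.32 and 1, 1 record per symbol, centring on the median, pseudocounts of 1 and 0.1, unmatched random lists, other backgrounds and lists without their largest member. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The list tests and the trend removal were tested on simulated data for the cocaine against saline comparison with 12566 genes. The random-list test called 4 of 4 lists shifted by 0.1, 3 of 3 shifted by 0.2, 3 of 3 shifted by 0.4 and 0 of 20 unshifted lists. In the same simulation cameraPR at 0.01 called 3 of 4, 3 of 3, 3 of 3 and 0 of 20. The simulated GC trend went from a rho of -0.59 to -0.01 after removal, and genes shifted by 0.4 kept a median of 0.40. The simulated lists were drawn at random, so the unshifted ones obeyed the assumption of the random-list test, and few calls among them were bound to follow. Real lists hold related genes, and the simulation does not show how often such lists are called falsely. Nor does it show how trend removal acts on a list of unusual GC content or length.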

Results

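Gene expression was measured by RNA sequencing in the nucleus accumbens, a ventral striatal part of the reward circuit, of C57BL/6 mice. The animals received 7 daily intraperitoneal injections of cocaine at 20 mg/kg or of saline, and per the labels the tissue belonged to a time point 4 h into withdrawal. The labels list 3 cocaine and 3 saline libraries. They do not say whether a library came from a single animal or from pooled tissue, so any spread between these libraries may be technical. How the authors' test estimated that spread is not given, so what variation the deposited p-values reflect is unknown. The authors' deposited table gives 1 FPKM value per group and gene record, with a log2 fold change, a p-value and a q-value. It gives no value per library, so no SD or range between replicates stands beside the values, and the read depth of the libraries is unknown. Of 21540 records, 14959 were marked as tested, 6271 were marked as not tested, 217 as failed, 88 as holding too little data and 5 as holding too much.

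The series title names Tet1, an enzyme that oxidises 5-methylcytosine, and its product 5-hydroxymethylcytosine in the action of cocaine, and the comparison asked which accumbens transcripts differed after repeated cocaine. In the cocaine group the mitochondrially encoded mRNAs rose together, led by mt-Nd5 with a log2 fold change of 0.43 in the authors' deposited table. Of 20 measured immediate-early genes 5 fell, among them Nr4a1 (-0.49), Junb (-0.35) and Egr1 (-0.24), and 15 did not pass, with a list median of -0.15 (adjusted gene-permutation p = 0.00187). The endothelial tight junction gene Cldn5 also fell (-0.45). The NMDA receptor subunits Grin2a (0.28) and Grin2b (0.22) rose by small amounts. Ttr, which encodes a carrier of thyroid hormone and retinol made abundantly by choroid plexus, stood at 0.668 FPKM in the saline group and 10.8 FPKM in the cocaine group. Tet1 did not pass the threshold.

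By the authors' deposited q-values, 184 of the 14959 tested records passed q < 0.05, of which 78 were higher and 106 lower after cocaine. At an unadjusted p under 0.05 the deposited table held 861 tested records. Most changes were small. Of the 184, 157 had an absolute log2 fold change under 0.32 and 49 under 0.1, while only Ttr (4.02) and Thbs4 (-1.51) reached 1. With a pseudocount of 1 they stood at 2.83 and -0.60, so the size of the Thbs4 change rests on a value near the floor (0.386 FPKM after cocaine). The median of the rises was 0.14 and that of the falls was -0.14. Among 12825 tested genes of at least 1 FPKM in the higher group, 89.5% lay within 0.2 of 0, the median log2 fold change was -0.02 and 40.7% lay above 0 (exact 95% binomial interval 39.8 to 41.5, as a description, since genes are not replicates).

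**Figure D1:**
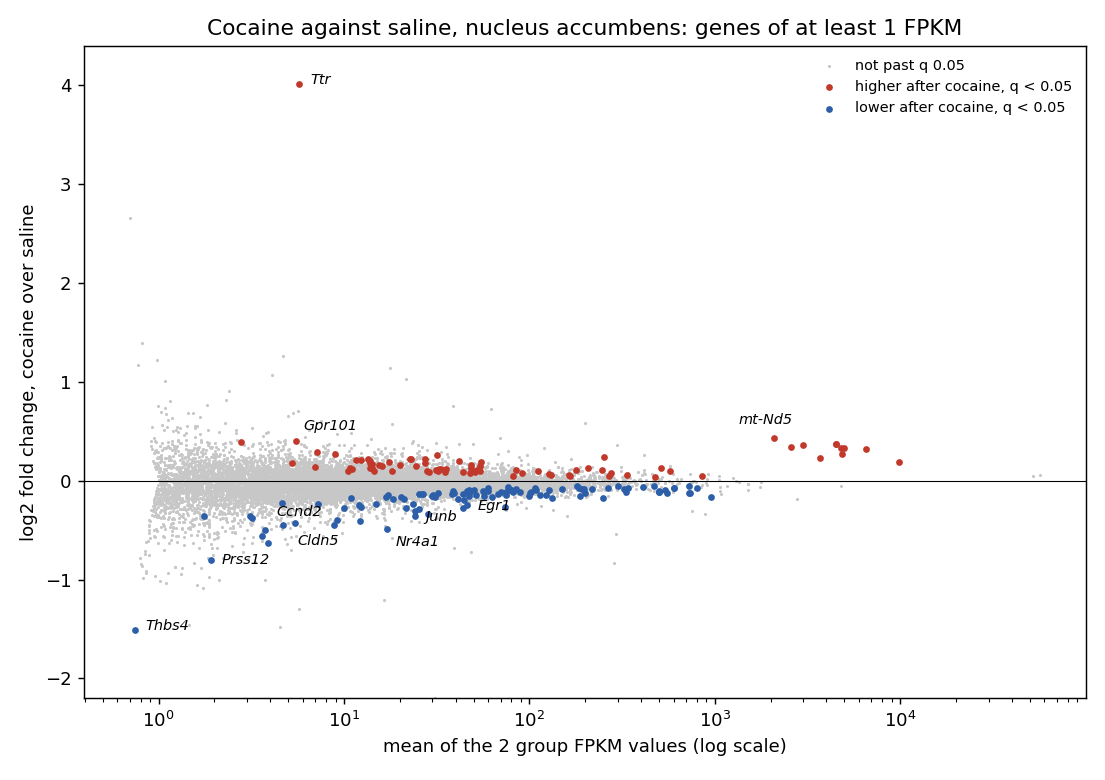
Log2 fold change, cocaine over saline, against the mean of both group FPKM values on a log axis, for each tested gene of at least 1 FPKM in the higher group. Red points are higher and blue points lower after cocaine at q < 0.05 in the authors' deposited table, grey points did not pass, and the red point at 4.02 is Ttr.

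Outside the mitochondrial genome, the largest named rises past the threshold in the authors' deposited table were Ttr (16.2-fold), Gpr101 (4.72 to 6.25 FPKM), Plcxd2 (2.41 to 3.16 FPKM) and Dio2 (6.42 to 7.84 FPKM). Gpr101 encodes an orphan G-protein-coupled receptor and Dio2 the deiodinase that makes active thyroid hormone. Their deposited q-values were 8.43e-08 for Gpr101, 8.85e-05 for Plcxd2 and 2.21e-05 for Dio2, and that of Ttr was listed as 0.

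Among genes with a proper name, the largest falls in the authors' deposited table were Thbs4, a secreted thrombospondin (1.10 to 0.386 FPKM, q = 2.46e-07), Prss12, the extracellular protease neurotrypsin (2.43 to 1.39 FPKM, q = 7.99e-05), and Nxph3, a neurexin ligand (4.70 to 3.03 FPKM, q = 5.05e-05). The log2 fold change of Prss12 was -0.80 as deposited and -0.52 with a pseudocount of 1. Cd24a, Sox11 and Ccnd2, genes abundant in immature neurons or their progenitors, fell by 0.56, 0.43 and 0.39 on the log2 scale. Cxcl12, a chemokine, fell by 0.50 and Lor, known as a protein of the cornified skin envelope, by 0.45. The deposited q-values of these 5 genes were 0.0138 for Cd24a, 0.00290 for Sox11, 0.0205 for Cxcl12 and 0.0210 for Lor, and that of Ccnd2 was listed as 0. Cldn5 and Nr4a1 completed the 10 named falls. A record without a proper name, 3110035E14Rik (-0.41, q = 4.71e-11), fell by more than Ccnd2 and was passed over by the naming rule.

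Of 28 gene lists fixed before the data were examined, 5 had a median log2 fold change outside that of random lists matched on mean FPKM, a permutation of gene labels and not of libraries. These were the immediate-early, endothelial and mural, mitochondrially encoded, microglial and glutamate receptor lists. By Fisher's exact test of calls against the other tested genes, 3 lists held more calls than the background: the mitochondrially encoded mRNAs (adjusted p = 5.93e-16), the immediate-early genes (adjusted p = 0.000105) and the glutamate receptor subunits (adjusted p = 0.00274). That test counts rises and falls together and was not matched on expression, GC content or transcript length. Called rises had long transcripts (median 7077 bases, against 3403 for genes not called), so the excess of glutamate receptor calls may follow from length.

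**Figure D2:**
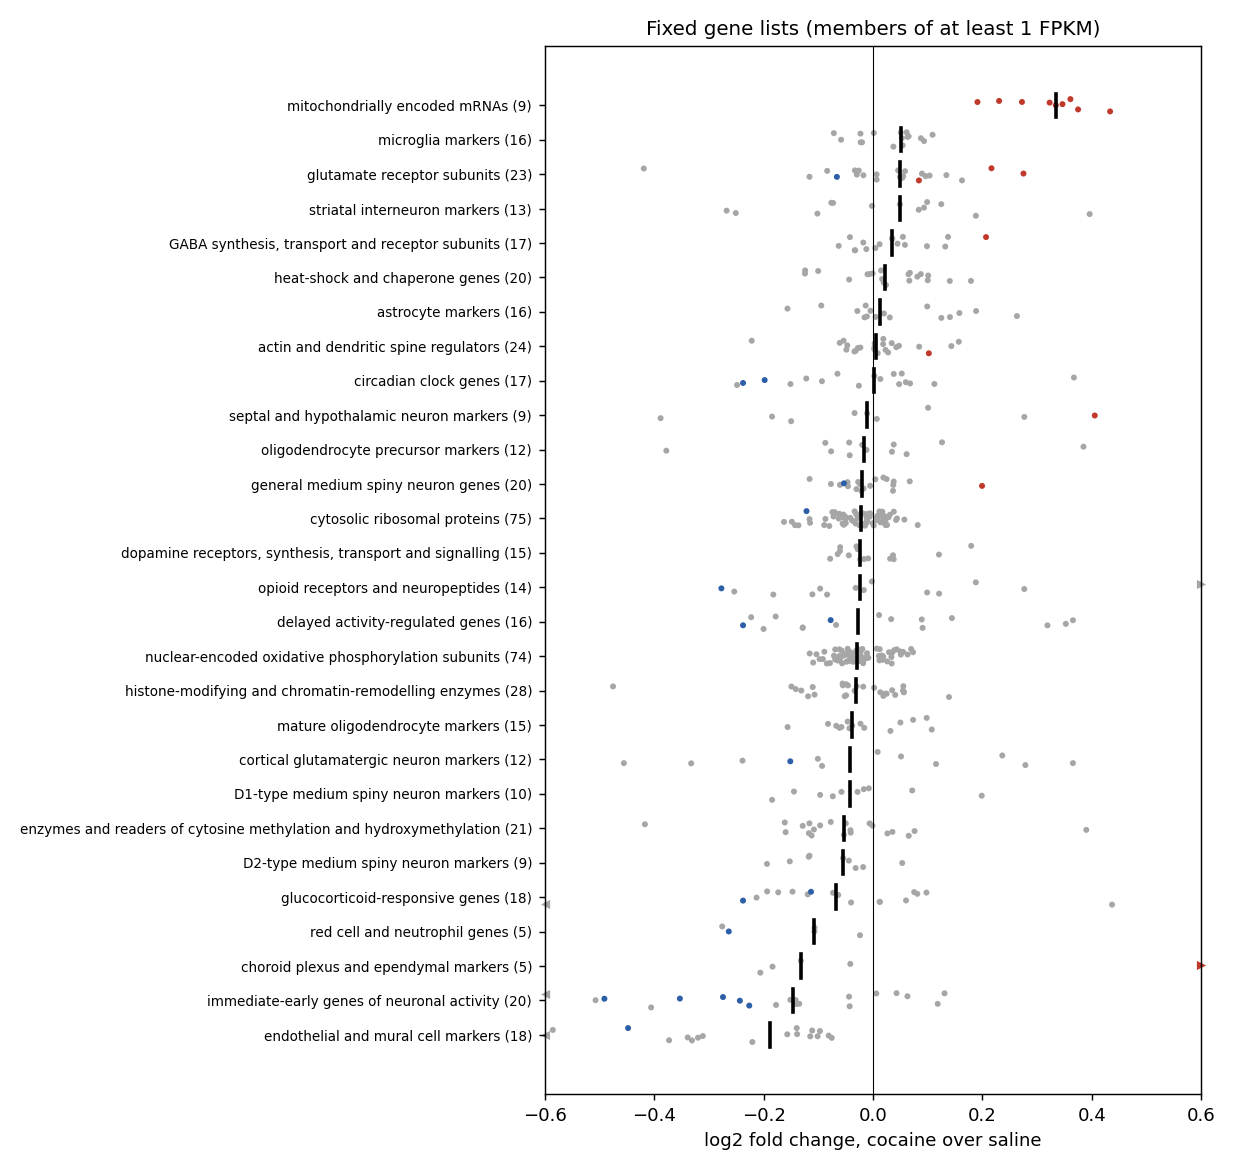
Log2 fold change, cocaine over saline, of each member of the 28 fixed gene lists, with the number of members of at least 1 FPKM in parentheses. Points are genes (red higher, blue lower at q < 0.05 in the authors' deposited table, grey not past the threshold), black bars are list medians, and arrowheads at the edges mark genes beyond 0.6 in either direction; the highest median, 0.33, belongs to the mitochondrially encoded mRNAs and the lowest, -0.19, to the endothelial and mural markers.

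Of 20 measured immediate-early genes, which neurons transcribe within minutes of activity, 5 fell, 0 rose and 15 did not pass in the authors' deposited table. The 5 were Nr4a1 (19.9 to 14.2 FPKM, q listed as 0), Egr1 (49.9 to 42.1 FPKM, q = 7.52e-13), Junb (27.0 to 21.1 FPKM, q = 1.94e-09), Egr4 (10.9 to 9.01 FPKM, q = 0.0198) and Fosl2 (4.99 to 4.27 FPKM). Adjusted over the list alone, 6 members were lower, the sixth being Arc (17.6 to 15.6 FPKM, deposited q = 0.338). The list median was -0.15 (adjusted gene-permutation p = 0.00187). By the authors' deposited test Fos (3.36 and 3.03 FPKM, p = 0.577) and Fosb (2.67 and 2.89 FPKM, p = 0.251) did not pass, nor did Homer1, Egr2, Egr3 and Npas4, whose deposited log2 fold changes lay between 0.01 and 0.13. Endothelial and mural markers, with a median of -0.19, were lower in the same group.

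Delayed activity-regulated genes gave 2 falls, 0 rises and 14 members not passing in the authors' deposited table, and 2 higher and 4 lower when adjusted over the list alone. Vgf, a neurosecretory peptide precursor, went from 110 to 104 FPKM (q = 0.0121; log2 fold change -0.08, and -0.0095 with the GC and length trend removed), and Per1, which is also a clock gene, from 25.5 to 21.7 FPKM (q = 0.0212). The list median of -0.03 and its mean of 0.01 differed in sign, and the median did not stand apart (adjusted gene-permutation p = 0.944). Among genes of at least 5 FPKM the median was -0.10 (adjusted gene-permutation p = 0.0104), with the GC and length trend removed it was 0.02 (adjusted gene-permutation p = 0.652), and cameraPR gave an adjusted p of 0.523 at a preset correlation of 0.01 and 0.643 at 0.05. Bdnf, at 0.415 and 0.388 FPKM in the authors' deposited table (p = 0.773), was below the expression minimum.

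All 18 measured endothelial and mural cell markers had deposited log2 fold changes below 0, with a median of -0.19 (adjusted gene-permutation p = 0.00187). Only Cldn5 passed on its own in the authors' deposited table (10.2 to 7.46 FPKM, q = 0.00123). Adjusted over the list alone, Col4a1, a basement membrane collagen, was also lower (2.82 to 2.26 FPKM). The list no longer stood apart among genes of at least 5 FPKM, with a median of -0.11 and an adjusted gene-permutation p of 0.0693. Blood transcripts gave a median of -0.11 over 5 genes (adjusted gene-permutation p = 0.147), with Hba-a2, an alpha globin, at 80.9 and 67.4 FPKM (q = 0.0335) as the only fall and 2 members lower when adjusted over the list alone. With cameraPR the blood list was lower (adjusted p = 0.00479 at a preset correlation of 0.01 and 0.0110 at 0.05), and all 5 members lay below 0, but the median was -0.06 with the GC and length trend removed (adjusted gene-permutation p = 0.124). Hba-a2 has a near-identical copy, Hba-a1, and reads could be divided between them, so its value is uncertain.

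All 9 mitochondrially encoded mRNAs with a tested value rose in the authors' deposited table, each with a q listed as 0 and each also past the threshold adjusted over the list alone. The list median was 0.33 (adjusted gene-permutation p = 0.00187). mt-Nd5 went from 1783 to 2408 FPKM, mt-Nd4l from 3915 to 5077, mt-Nd6 from 2608 to 3349, mt-Nd2 from 2265 to 2880, mt-Nd4 from 4427 to 5582 and mt-Cytb from 5835 to 7299. Their share of summed FPKM was 6.74% in the saline group and 8.15% in the cocaine group. The other 4 mitochondrial mRNAs, mt-Co1, mt-Co3, mt-Atp6 and mt-Atp8, are listed at 0 in both groups with a mark for too much data, which is a failed estimate. The records Gm10222 and Gm10925, predicted genes that rose beside them, have group values close to those of mitochondrial mRNAs (3917 and 5079 FPKM for Gm10222, next to mt-Nd4l), so reads could be shared between near-identical copies and these values are uncertain. Nuclear genes for the same respiratory chain gave 0 calls among 74 by the authors' deposited test (1 higher and 5 lower at an unadjusted p under 0.05), 3 lower when adjusted over the list alone, and a median of -0.03 (adjusted gene-permutation p = 0.499).

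Of 23 glutamate receptor subunits, 3 rose, 1 fell and 19 did not pass in the authors' deposited table, and adjusted over the list alone 4 were higher and 3 lower. The NMDA receptor subunits Grin2a (8.11 to 9.82 FPKM, q = 0.0162) and Grin2b (12.5 to 14.6 FPKM, q = 0.00687) and the AMPA receptor subunit Gria2 (89.0 to 94.3 FPKM, q = 0.0216) rose, but the log2 fold change of Gria2 was 0.08 as deposited and 0.0043 after removal of the GC and length trend described next. The kainate receptor subunit Grik5 fell (78.7 to 75.2 FPKM, q = 0.0447), a direction that it did not keep after removal of the same trend (0.0048). The list median was 0.05 (adjusted gene-permutation p = 0.0140). The call ended after removal of that trend, with a median of 0.03 and an adjusted gene-permutation p of 0.485, and with cameraPR at a preset correlation of 0.05 (adjusted p = 0.107). GABA synthesis, transport and receptor genes gave 1 rise among 17, Gabrb1 (11.5 to 13.3 FPKM, q = 0.0255), also 1 when adjusted over the list alone, and a median of 0.04 (adjusted gene-permutation p = 0.0700). The log2 fold change of Gabrb1 went from 0.21 to 0.13 with the trend removed. That list passed among genes of at least 5 FPKM (adjusted gene-permutation p = 0.0370) and with cameraPR at 0.01 (adjusted p = 0.0245) but not at 0.05 (adjusted p = 0.102), nor after trend removal, where its median was 0.02 (adjusted gene-permutation p = 0.629).

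Genes with GC-poor and long transcripts tended to be higher after cocaine. The 75 called rises with a matched transcript had a median GC content of 46.2% and a median length of 7077 bases. The 104 called falls had 56.2% and 3131.5 bases (two-sided permutation test, p = 1e-05 for each, the smallest that 100000 permutations can give). That test permuted rise and fall labels over genes, not libraries, so it describes these libraries only. Across 12566 genes, which are not independent replicates, Spearman's rho of the fold change was -0.30 with GC content and 0.18 with length. After the trend was removed, in a comparison added after seeing the data, the list median was -0.11 for the immediate-early genes, -0.16 for the endothelial and mural markers and 0.26 for the mitochondrially encoded mRNAs, each with an adjusted gene-permutation p of 0.00187. It moved 8 of the 39 named genes past the threshold by over 1.5 times or turned them, and changed the sign of the median of 11 lists, 0 of which passed before or after.

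**Figure D3:**
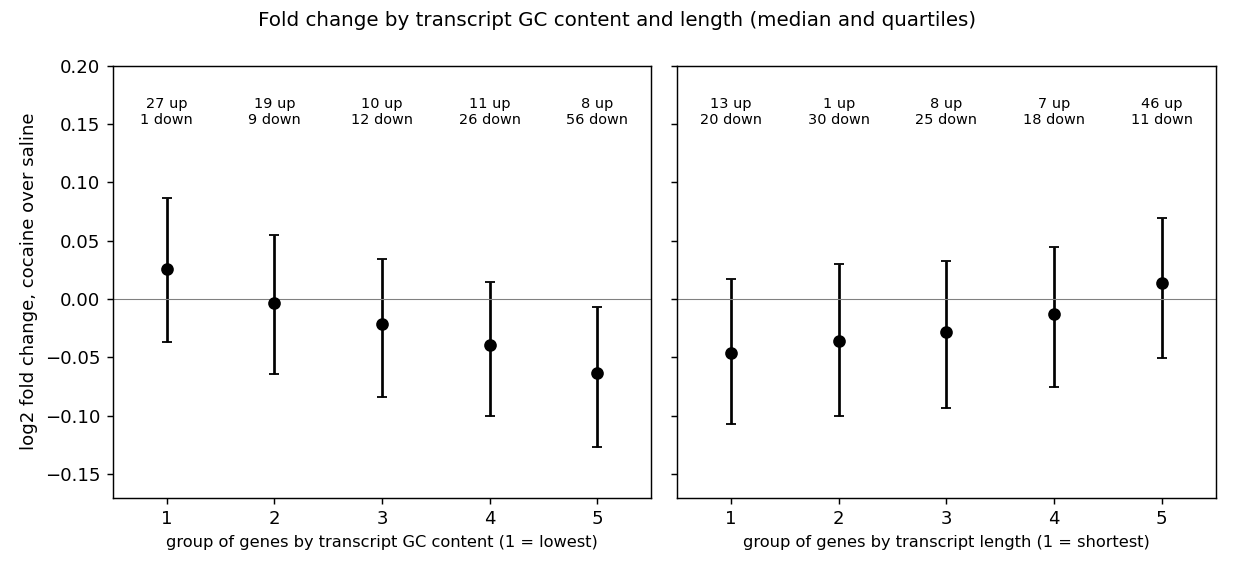
Median log2 fold change, cocaine over saline, with lower and upper quartiles as bars, in 5 equal groups of 12566 genes by transcript GC content (left) and transcript length (right); the numbers above are genes called higher and lower at q < 0.05. The median fell from 0.03 in the group of lowest to -0.06 in the group of highest GC content, and was -0.05 in the shortest and 0.01 in the longest transcripts.

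Tet1 stood at 1.58 FPKM in the saline group and 2.07 FPKM in the cocaine group (log2 fold change 0.39, p = 0.221), which did not pass in the authors' deposited table. With a pseudocount of 1 its log2 fold change was 0.25. Tet2 (6.56 and 6.86 FPKM, p = 0.132) and Tet3 (7.88 and 8.08 FPKM, p = 0.720) did not pass the authors' deposited test either. Among 21 enzymes and readers of cytosine methylation and hydroxymethylation, 0 passed by the authors' deposited test, 1 was higher at an unadjusted p under 0.05, 0 passed adjusted over the list alone, and the median was -0.05 (adjusted gene-permutation p = 0.471). The 28 histone-modifying and chromatin-remodelling enzymes gave 0 calls by the same test, 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, and a median of -0.03 (adjusted gene-permutation p = 0.793).

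Genes that mark medium spiny neurons, the main neurons of the region, differed little. Drd1a was at 65.0 and 63.8 FPKM (p = 0.221) and Drd2 at 91.2 and 88.5 FPKM (p = 0.173) in the authors' deposited table. By the authors' deposited test the D1-type list gave 0 calls among 10 (1 lower at an unadjusted p under 0.05, 1 lower adjusted over the list alone, median -0.04, adjusted gene-permutation p = 0.682). The D2-type list gave 0 among 9 (2 lower at an unadjusted p under 0.05, 1 lower adjusted over the list alone, median -0.05, adjusted gene-permutation p = 0.499). With cameraPR the D2-type list was lower (adjusted p = 0.00926 at 0.01 and 0.0370 at 0.05), with 8 of 9 members below 0, while its median after trend removal was 0.01. Of 20 general medium spiny neuron genes, Ano3, a channel-like protein, rose (39.0 to 44.8 FPKM, q = 0.0129), and Scn4b, a sodium channel beta subunit, fell (183 to 177 FPKM, q = 0.000420; log2 fold change -0.05, and -0.02 with the GC and length trend removed). Adjusted over the list alone, 2 of these genes were higher and 2 lower, and the median was -0.02 (adjusted gene-permutation p = 0.944). Dopamine receptor, synthesis and signalling genes gave 0 calls among 15 by the authors' deposited test (1 higher and 3 lower at an unadjusted p under 0.05, 0 adjusted over the list alone) with a median of -0.02 (adjusted gene-permutation p = 0.944). Interneuron markers gave 0 among 13 (1 higher and 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone) with a median of 0.05 (adjusted gene-permutation p = 0.161).

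Cortical neuron markers, septal and hypothalamic neuron markers, opioid receptor and neuropeptide genes, and choroid plexus and ependymal markers gave single calls per list in the authors' deposited table. Members of these neuron lists may also be expressed within the region. Among 12 cortical glutamatergic markers, Slc17a7, a vesicular glutamate transporter, fell (49.9 to 44.9 FPKM, q = 3.70e-05; log2 fold change -0.15, and -0.07 with the GC and length trend removed), also the 1 call adjusted over the list alone, with a list median of -0.04 (adjusted gene-permutation p = 0.853). Among 9 septal and hypothalamic markers, Gpr101 rose, 2 were higher adjusted over the list alone, and the median of -0.01 and mean of 0.003 differed in sign (adjusted gene-permutation p = 0.944), while cameraPR placed the list higher (adjusted p = 0.0170 at 0.01 and 0.0489 at 0.05). Among 14 opioid receptors and neuropeptides, the peptide precursor Cck fell (48.0 to 39.6 FPKM, q = 0.0127), 2 were higher and 1 lower adjusted over the list alone, and the median of -0.02 and mean of 0.03 differed in sign (adjusted gene-permutation p = 0.944). Of 5 measured choroid plexus and ependymal markers only Ttr passed, also adjusted over the list alone, and the median of -0.13 and mean of 0.69 differed in sign, as Ttr alone lay above 0 (adjusted gene-permutation p = 0.308), and cameraPR placed the list higher at 0.01 (adjusted p = 0.0334) but not at 0.05 (adjusted p = 0.0673). Other choroid plexus genes lay near the floor, such as Kcnj13 (0.0658 and 0.581 FPKM, p = 0.0890) and Folr1 (0.234 and 0.618 FPKM, p = 0.490), and did not pass the authors' deposited test.

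Glial lists gave 0 calls by the authors' deposited test, and 0 adjusted over each list alone. Microglial markers had a median of 0.05 over 16 genes, with 0 at an unadjusted p under 0.05 (adjusted gene-permutation p = 0.0213). That call ended with cameraPR (adjusted p = 0.178 at a preset correlation of 0.01 and 0.379 at 0.05) and against unmatched random lists (adjusted gene-permutation p = 0.0806). Astrocyte markers had a median of 0.01 over 16 genes (3 higher and 2 lower at an unadjusted p under 0.05, adjusted gene-permutation p = 0.311). Mature oligodendrocyte markers had a median of -0.04 over 15 genes (2 higher, adjusted gene-permutation p = 0.585), and oligodendrocyte precursor markers -0.02 over 12 genes (1 higher, adjusted gene-permutation p = 0.944).

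The remaining lists held few changes in the authors' deposited table. Among 17 circadian clock genes, Nr1d1, which encodes the repressor REV-ERB alpha (47.4 to 41.3 FPKM, q = 3.70e-05; log2 fold change -0.20, and -0.13 with the GC and length trend removed), and Per1 fell, also the 2 calls adjusted over the list alone, and the median of 0.003 and mean of -0.02 differed in sign (adjusted gene-permutation p = 0.585). Among 18 glucocorticoid-responsive genes, Per1 and the metallothionein Mt1 (517 to 478 FPKM, q = 0.00118) fell, 1 member was higher and 3 lower adjusted over the list alone, and the median was -0.07 (adjusted gene-permutation p = 0.308), or -0.11 among genes of at least 5 FPKM (adjusted gene-permutation p = 0.0104). It was -0.03 with the GC and length trend removed (adjusted gene-permutation p = 0.485), and the glucocorticoid list did not pass with cameraPR (adjusted p = 0.0786 at 0.01 and 0.219 at 0.05). Among 24 actin and dendritic spine regulators, the kinase subunit Camk2a rose (554 to 595 FPKM, q = 0.00915), 2 were higher and 1 lower adjusted over the list alone, and the median was 0.01 (adjusted gene-permutation p = 0.298). Among 75 cytosolic ribosomal proteins, Rplp1 fell (770 to 708 FPKM, q = 1.10e-05; log2 fold change -0.12, and -0.06 with the GC and length trend removed), also the 1 call adjusted over the list alone, and the median was -0.02 (adjusted gene-permutation p = 0.944). Heat-shock and chaperone genes gave 0 calls among 20 by the authors' deposited test (4 higher at an unadjusted p under 0.05, 1 higher adjusted over the list alone) and a median of 0.02 (adjusted gene-permutation p = 0.147). The chaperone list passed among genes of at least 5 FPKM (median 0.04, adjusted gene-permutation p = 0.0104) and with cameraPR (adjusted p = 0.00754 at 0.01 and 0.0489 at 0.05), but not after trend removal (median 0.05, adjusted gene-permutation p = 0.0672).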

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

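The vascular test of the immediate-early genes, the choroid test on the fixed list and the test of nuclear respiratory chain genes were chosen only after the result was seen, and removal of the GC and length trend was added after seeing the data. With group values alone, other splits of the libraries were out of reach.

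Records of at least 100 FPKM that the authors' deposited table marks as failed, and so left untested, were looked at for cocaine values at least 0.1 above saline on the log2 scale. Of 16 failed records of that level 3 met this and 0 lay 0.1 or more below, with a median log2 ratio of 0.02. Kif1b, a kinesin motor, was at 138 and 150 FPKM, a log2 ratio of 0.12. Mtap1a, a microtubule-associated protein, was at 153 and 178 FPKM (0.21), and Mtap2, another, at 191 and 219 FPKM (0.19). No deposited test exists for them, and group values marked as failed may be unreliable. Whether these ratios follow the GC and length trend was not examined.

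Immediate-early genes fell as a list, with a median of -0.15. A GC and length trend as the whole cause is argued against by the values: with the trend removed the median was -0.11, at percentile 0 of random lists matched on FPKM, GC content and length. A lower share of vascular cells, which may also express some of these genes, cannot be told apart from a change in neurons. The 5 members taken as mostly expressed in neurons were Arc, Egr2, Egr3, Egr4 and Npas4. They had a median of 0.01, at percentile 67.15, but went both ways, from -0.27 for Egr4, which passed the threshold, to 0.06 for Npas4. They were chosen after the values were seen, and Egr1, which fell (-0.24), was not among them. The median of so few genes depends on that choice, so this subset cannot settle the question. A response to repeated cocaine, the difference the design names, also stays open and was not tested apart from these.

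Ttr was 16.2-fold higher, while no other gene past the threshold rose by more than 0.43 on the log2 scale. Choroid plexus tissue carried into some cocaine libraries is a candidate explanation that the values leave open. Of the other 10 choroid genes of the fixed list, 8 were higher after cocaine, against a median of 4 in random lists matched on FPKM (percentile 98.3, two-sided gene-permutation p = 0.0594). Their median log2 fold change was 0.36, at percentile 99.92 (two-sided gene-permutation p = 0.00180), with Kcnj13 at 0.0658 and 0.581 FPKM. The only ones that reached 1 FPKM, Clic6 (6.42 and 5.65 FPKM) and Kl (1.46 and 1.42 FPKM), were not higher. Both stood above Ttr in the saline group (0.668 FPKM), so other cells may express them, and they cannot weigh against carried-over choroid plexus. The remaining members of the fixed choroid plexus and ependymal list were not counted as choroid genes and so were left out of these 10. None of those left out was higher after cocaine, but a marker of ependymal cells need not rise with choroid plexus tissue. Among them, Ccdc153 had a deposited log2 fold change of -0.56, Tmem212 of -0.82 and Mia1 of -0.01. The percentiles of the 10 genes therefore rest on which members are counted as choroid genes. A second set of choroid markers gave 6 higher of 13, at percentile 50.01, the median of random lists, and a median log2 fold change of -0.0011, at percentile 60.26 (two-sided gene-permutation p = 0.795). Its 3 members that reached 1 FPKM, Car12 (18.9 and 18.7 FPKM), Igf2 (9.25 and 6.84 FPKM) and Ace (1.83 in both groups), were not higher either, though other cells may express them. Most members of both sets lie near the floor, with median levels of 0.240 and 0.209 FPKM, where ratios may rest on few reads, and the sets differ. Neither decides, and the bound set for the second could not exclude the explanation; a change of Ttr within the tissue also stays open.

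Mitochondrially encoded mRNAs rose by a median of 0.33. The GC and length trend seen over all genes is argued against as the whole cause, since the median after its removal was 0.26, at percentile 100 of matched lists. An effect of GC content or length particular to such abundant transcripts was not tested and stays open. A joint rise of the whole respiratory chain is also argued against, since nuclear-encoded subunits had a median of -0.03, at percentile 14.2. A difference between libraries in RNA quality or preparation could also move mitochondrial transcripts and cannot be examined without values per library, so this stays open beside a response to cocaine.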

How the results depend on the processing

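The GC and length corrections were added after seeing the data. No paired analysis was possible because the table holds only group values; for the same reason leaving out each replicate, a pseudocount per library and a replicate block were not run. Of 184 calls (78 higher, 106 lower), 119 (51 and 68) stood at q < 0.01, 27 (11 and 16) at an absolute log2 fold change of at least 0.32 and 2 (1 and 1) at 1, fewer by construction, and the counts under the other 8 settings stayed within 1.5 times. Centring, 1 record per symbol and trend removal kept the deposited q, so their totals of 184, 184 and 179 could not test the calls. Under centring and trend removal only directions could turn. The median of the endothelial and mural list was -0.11 at a minimum of 5 FPKM (adjusted p = 0.0693), where fewer genes entered. The microglial median, 0.052, no longer passed against unmatched lists (adjusted p = 0.0806), nor did the list with cameraPR (adjusted p = 0.178 at a correlation of 0.01 and 0.379 at 0.05). The glutamate receptor median was 0.026 after removal of the trend (adjusted p = 0.485), and cameraPR at 0.05 gave 0.107; for the microglial and cameraPR results the cause was not tested. The other 39 of 45 settings of the 5 lists that stood apart kept direction and threshold. Centring on the median shifts a list and its random lists alike, so the p of that setting could not change. Among the other 23 lists, 11 settings passed in the direction of the median (delayed activity, D2-type, blood, GABA, glucocorticoid and chaperone lists), cameraPR passed against it for the septal and hypothalamic (0.0170 and 0.0489) and choroid (0.0334) lists, 189 settings did not pass, and the calls of 1 list, opioid receptors and neuropeptides, passed Fisher's exact test at q < 0.10 only. Of named genes, Grik5 reversed after trend removal (0.0048) and Drd2, not called, went from -0.044 to 0.017, while the other settings kept the direction, though Gria2 (0.0043) and Vgf (-0.0095) came close to 0 after trend removal and a pseudocount of 1 brought Thbs4 from -1.51 to -0.60 and Prss12 from -0.80 to -0.52, as their FPKM values are close to the pseudocount. Among called genes outside the naming rule, Camkv (0.02) and Rnf187 (0.01) reversed after trend removal. Unknown depth limits what can be said of genes near the floor.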

Other observations

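The neuroblast, channel and tubulin lists were chosen only after the called genes were seen, and their p-values were adjusted over the lists added then. The called genes that prompted each list were left out of it.

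Actb, a cytoplasmic actin, went from 1014 to 903 FPKM in the authors' deposited table (q = 5.76e-11), and the tubulins Tubb2a from 208 to 191 (q = 1.65e-08), Tubb2b from 119 to 108 (q = 7.83e-08) and Tubb5 from 197 to 178. The other 9 measured tubulins and actins gave 0 calls by the authors' deposited test (4 lower at an unadjusted p under 0.05) and 4 lower adjusted over the list alone. Their median was -0.08 (adjusted gene-permutation p = 0.0477), and with the GC and length trend removed it was -0.03 and no longer stood apart (adjusted gene-permutation p = 0.254). The voltage-gated channel genes Kcna1 (27.0 to 28.8 FPKM, q = 0.00115), Kcna2 (10.8 to 12.5 FPKM, q = 0.0143) and Cacna1e (30.1 to 32.5 FPKM, q = 4.36e-08) rose in the same table. The other 25 measured pore-forming subunits gave 0 calls by the authors' deposited test (3 higher at an unadjusted p under 0.05) and 2 higher adjusted over the list alone. Their median was 0.04 (adjusted gene-permutation p = 0.00800), and 0.03 with the trend removed, where it no longer stood apart (adjusted gene-permutation p = 0.215). Outside these lists, Lars2, the mitochondrial leucyl-tRNA synthetase, rose from 233 to 275 FPKM, and Unc13c, a synaptic vesicle priming protein, from 21.3 to 24.9 FPKM, each with a deposited q listed as 0.

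Sox11, Ccnd2, Cd24a and Tubb2b, which fell, are abundant in immature neurons, and fewer cells of the nearby subventricular zone or migrating neuroblasts in the cocaine tissue may account for it. Other neuroblast markers were tested for the same direction. Of 11 measured, 10 had a deposited log2 fold change below 0, and the median was -0.21, at percentile 0 of random lists matched on FPKM (adjusted gene-permutation p = 0.000800). After removal of the GC and length trend the median was -0.14, at percentile 0.01. None passed q < 0.05 alone, 4 were lower at an unadjusted p under 0.05 and 3 were lower adjusted over the list alone; Sox4 was at 9.05 and 6.79 FPKM and Dlx1 at 15.2 and 12.2 FPKM, while Dcx was at 4.51 and 4.60 FPKM. Some of these genes, such as Stmn1 and Dlx6, are also expressed by mature neurons of the region. Most of these values go with the hypothesis, but Dcx, a neuroblast marker, was not lower, and the hypothesis does not account for that. Tubb2b (-0.14) fell about as much as the tubulins Tubb2a (-0.12) and Tubb5 (-0.15), so its fall need not come from immature neurons. A change of expression within cells stays open, and endothelial markers were lower in the same group.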
